A study of Gallus gallus with 168 samples.

How the data were processed

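The study sequenced RNA from single slices of early chicken embryos, 168 libraries in 5 series: antero-posterior slices of HH1 (10 libraries), HH2 (10), HH3 (12) and HH5 (100), with 2 embryos each, and left-right slices of 1 HH5 embryo (36). Per the labels' protocols, HH5 embryos were frozen in embedding medium and cut into slices of 100 µm, while the earlier embryos were cut by hand into pieces of even length. RNA was extracted from each piece with a micro-scale column kit. Libraries were made with a kit that sequences the 3' ends of messenger RNA and followed its instructions for low input, per the labels' protocols. Such counts reflect transcript numbers with little effect of gene length, depend on the annotation of 3' ends, and at low input can hold many copies of the same molecule. Whether molecular identifiers were used, the aligner, the annotation release and the strand setting are not given in the sources used here.

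The authors deposited 1 table of raw read counts per Ensembl gene identifier, with spike-in and summary lines, and per the submitters' processing notes it was made on the galGal6 build with HTSeq 0.13.5 and SAMtools 1.10. The table holds 24356 gene identifiers, 92 ERCC and 7 SIRV spike-ins and 5 summary lines of the counter. Of all reads in it, 56.6% were assigned to genes, 26.7% lay outside annotated features, 15.3% aligned to several places, 1.18% were ambiguous between genes, 0.103% were ERCC and 0.113% SIRV reads. Lines that name no gene stayed out of library sizes and tests. Reads with several alignments form a line of their own, so members of gene families with near-identical 3' ends are undercounted, and the values of overlapping or antisense genes are uncertain because the strand setting is unknown. Each column carried the title of exactly 1 sample, and no column was left over.

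Groups, embryos and section numbers were taken from the labels. Titles number the sections without stating which end comes first, so no end was called anterior, posterior, left or right. The reference table in hand, for 25635 genes of the GRCg7b assembly, matched 0 of the identifiers, and it belongs to another build. Gene symbols, coordinates and the gene lists drawn up before the data were examined could therefore not be applied, and the planned tests of those lists were not run. The naming rule asked for genes with symbols. In its place up to 2 identifiers per direction and comparison are printed, those with the largest absolute log2 fold change among genes that passed, with a mean of at least 3 log2 CPM and the same sign in every embryo. This departs from the rule as first written. The gene with a different slope at HH2 and HH1 and the 4 genes of the HH1 middle comparison were chosen after their values were seen.

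Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were filtered by filterByExpr (minimum count 10, total 15), libraries scaled by TMM, and models fitted with glmQLFit (robust) and glmQLFTest. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes under 0.05 were called; all tests were two-sided. The SE of a log2 difference is its absolute value divided by the square root of the F statistic. CPM values printed are TMM-scaled. For HH5 ends and middle, the sections of each embryo were summed into 3 segments (sections 1 to 15, 16 to 30 and 31 to 46 of embryo 1, and 1 to 18, 19 to 36 and 37 to 54 of embryo 2). The 6 sums were fitted with embryo as a block, because the segments of an embryo come from the same animal. Deviations of these sums from the segment means correlated between segments of an embryo at 0.579, 0.505 and 0.642. Curves were natural cubic splines with 4 degrees of freedom over relative position, compared between embryos at 21 points. The left-right sides were compared with a spline of 3 degrees of freedom for distance from the centre. Slopes at HH1, HH2 and HH3 were fitted together over 32 libraries, with embryo as a block and 1 slope per stage. Stage sums of 8 embryos were fitted with stage alone, since embryo numbers of different stages mark different animals.

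Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE size factors, no count filter, no block (or a block, for stages), 5 segments in place of 3, sections as samples, other spline degrees, other curve correlations, shifted centres, single stages, and leaving out embryos or libraries below 10% of the median depth of their embryo. Spike-in scaling, library totals, covariates and the removal of particular libraries were added after seeing the data. The fits were tested on simulated data drawn from the means, library sizes and dispersions of these libraries, with 200 changed genes each. For the HH5 ends, over 13397 genes, 38% of the genes changed by 1 on the log2 scale and 65% of those changed by 2 were recovered. For the HH1 slope, over 9795 genes, the shares were 24% and 69%, and for the HH3 slope, over 9827 genes, 26% and 66%. For stage differences of HH3 and HH2, over 11980 genes, they were 1% and 34%. No 2 libraries of an embryo had identical counts in 3162 pairs, and the lowest chi-square per gene was 2.77, above the value near 1 that sampling noise alone gives. Intervals of counts cover counting error only, since reads made by PCR are not independent molecules.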

Results

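Spatial gene expression was measured in chicken (Gallus gallus) embryos during gastrulation by sequencing consecutive slices of single embryos one by one, an approach known as Tomo-seq. Stages follow the Hamburger and Hamilton (HH) series, in which HH1 precedes the primitive streak, HH2 and HH3 are streak stages and HH5 is the stage at which the head process forms. The antero-posterior slices of HH1, HH2 and HH3 came from hand dissection, with 2 embryos in each: 5 sections per embryo at HH1 and at HH2, and 6 per embryo at HH3. At HH5 the slices were cryosections of 100 µm, 46 from embryo 1 and 54 from embryo 2 along the antero-posterior axis, and 36 from 1 further embryo along the left-right axis. Together they make 168 libraries of 3' ends of messenger RNA. Gene counts had a median of 2707939 per library at HH1, 2660400 at HH2, 2782385 at HH3, 2295586 in the HH5 antero-posterior series and 2534052 in the left-right series. Depth ran from 277178 to 6344564 gene counts, apart from 1 HH2 library (embryo 2, section 4) with 4327. The labels number the sections without saying which end is anterior or left, so positions are given here as low-numbered and high-numbered. Genes are named by their Ensembl identifiers, because the deposited table does not pair them with symbols. The embryo was the replicate in the comparisons of HH5 antero-posterior segments and of stages. Curves and left-right comparisons were fitted over the sections of 1 embryo at a time, so their p-values measure the spread between sections of that embryo. Slopes were fitted over the sections of HH1, HH2 and HH3 together, so their p-values measure the spread of sections around the fitted lines, pooled over these stages.

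The first comparison asked how expression differed between the ends of the antero-posterior axis at HH5, with the sections of each embryo summed into low-numbered, middle and high-numbered segments. Of 14192 genes tested, 575 were higher in the high-numbered segment and 650 were higher in the low-numbered one. All 1225 had the same sign in both embryos, but the paired fit of these embryos can hardly call a gene of opposite signs, so this is no separate support. The median absolute log2 difference of these genes was 1.11, and 669 differed at least 2-fold. ENSGALG00000026467 rose from 4.18 ± 2.57 CPM, counts scaled to library size, in the low-numbered segment to 26.4 ± 9.32 in the middle and 156 ± 107 in the high-numbered segment (SD, n = 2 embryos), a log2 difference of 5.17 with an SE of 0.213. ENSGALG00000006346 followed the same course at a lower level, from 0.543 ± 0.194 to 25.1 ± 14.2 CPM (log2 difference 5.48, SE 0.318). In the opposite direction, ENSGALG00000030809 went from 63.9 ± 23.1 to 4.02 ± 1.80 CPM, with 19.6 ± 7.15 in the middle (log2 difference -4.06, SE 0.542). ENSGALG00000016600 went from 12.5 ± 0.273 to 0.739 ± 0.278 CPM (log2 difference -4.06, SE 0.308), with 28.2 ± 6.58 in the middle segment. The adjusted p-values of these 4 genes in edgeR's quasi-likelihood test were 5.97e-10, 8.50e-09, 0.0243 and 3.57e-07 in the order given. The fit of these sums leaves 2 residual degrees of freedom per gene. Such p-values therefore rest on a spread estimated with information from all genes, and not on the 2 embryos alone. With the outermost of 5 segments in place of 3, the log2 difference of ENSGALG00000016600 was -0.86 and no longer passed, and that of ENSGALG00000030809 was -3.57 and did not pass either. The fit treats the segments of an embryo as paired, and without that block edgeR called 0 genes, with 767 at an unadjusted p under 0.05, while DESeq2 with the block called 1451. By chance alone a share of about 0.05 of the genes tested reaches an unadjusted p under 0.05, here and in later comparisons.

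A second comparison set the middle of the axis against the mean of both ends, so a gene could pass while differing from only 1 of them. In the middle segment 195 genes were higher than the mean of the outer segments and 266 were lower, with a median absolute log2 difference of 0.82. ENSGALG00000016469 stood at 44 ± 14.1 CPM in the middle against 0.372 ± 0.401 and 12.1 ± 3.85 in the low-numbered and high-numbered segments (log2 difference 4.41, SE 0.237, adjusted p = 8.36e-08 in edgeR's quasi-likelihood test). ENSGALG00000001191 reached 107 ± 48.5 CPM in the middle and 15.6 ± 15.7 and 2.60 ± 1.19 outside it (log2 difference 4.26, SE 0.403, adjusted p = 0.0254 in the same test). Its call was lost without embryo 1 section 14, a library of 277178 gene counts, although the log2 difference was then 4.29. ENSGALG00000033171 had the reverse profile, with 3.73 ± 0.766 CPM in the middle and 20.3 ± 7.69 and 19.9 ± 12.6 at the ends (log2 difference -2.35, SE 0.241). ENSGALG00000005442 was likewise lowest in the middle, at 3.22 ± 1.18 CPM (log2 difference -1.89, SE 0.257). Without the block of embryo edgeR called 0 genes here too, with 344 at an unadjusted p under 0.05, and DESeq2 with the block called 600.

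**Figure D1:**
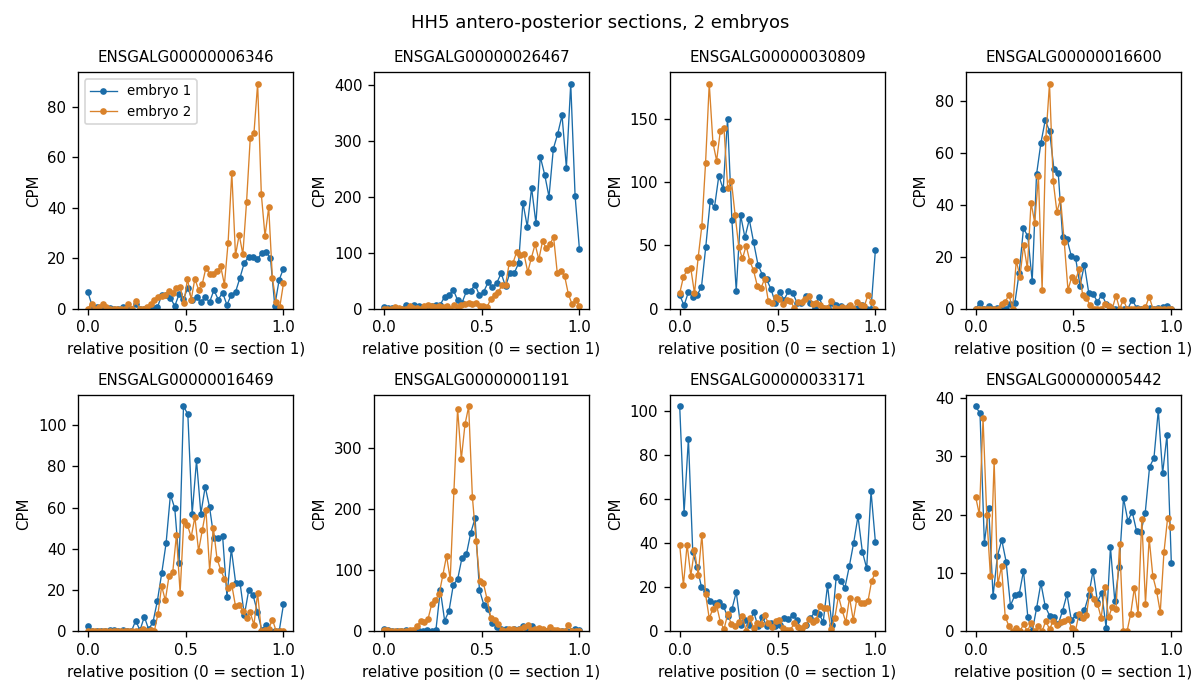
CPM (vertical axes, from 0) against relative position along the HH5 antero-posterior axis (horizontal axes, 0 is section 1) for the 8 genes named in the segment comparisons; each point is 1 section and each colour 1 embryo. ENSGALG00000016469 and ENSGALG00000001191 were highest in the middle segment of both embryos, and ENSGALG00000033171 and ENSGALG00000005442 were higher in both outer segments.

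Position was then followed section by section, by fitting a smooth curve to each gene in each embryo. Curves departed from flat for 3554 of 10737 genes in embryo 1 and for 4938 of 10175 in embryo 2. Counts for independent lists, here and later, take every gene as equally likely to be called, so lists can exceed them without a shared pattern. Both embryos called 2579 of the 9776 genes tested in each, against 1678 for independent lists. Of these, 2030 had curves that correlated across the embryos at 0.5 or more, which was 78.7% of the genes called in both against 28.7% when genes were paired at random. The largest class, 1134 genes or 55.9%, peaked in the low-numbered segment, with a median range of 1.86 on the log2 scale. A further 429 peaked in the middle segment and 467 in the high-numbered one, with median ranges of 1.52 and 1.19. The very first section held 702 of all peaks, whereas 235 fell at relative position 0.3 and only 7 at 0.1. Lowest points were also scarce just inside that end, with 12 at 0.1. The fitted splines bend little near their ends, so these positions partly follow the form of the curve and do not show separate locations of expression. The high-numbered end held 260 peaks at its last position. Lowest points lay at the first section for 836 genes, more than the peaks there, and in the low-numbered segment for 417 genes that peaked in the high-numbered segment, 381 that peaked in the middle and 320 that peaked in the low-numbered segment itself. In 80.9% of the 2030 genes the peaks of the embryos lay within 0.2 of the axis length of one another, while 147 of the genes called in both had curves of negative correlation.

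**Figure D2:**
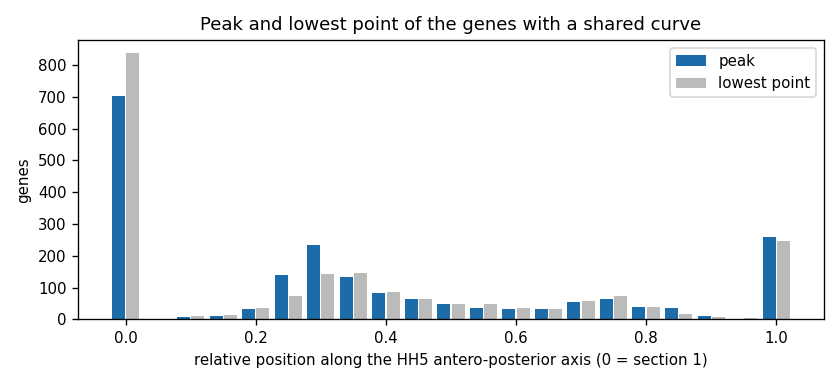
Number of genes (vertical axis) whose mean fitted curve has its peak (blue) or its lowest point (grey) at each relative position (horizontal axis) along the HH5 antero-posterior axis, for the 2030 genes with a curve shared by both embryos. Peaks of the fitted curves gather at the first section, around position 0.3 and at the last section, as do the lowest points. The form of the curves partly sets these positions.

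The left-right series asked how expression changed across the width of an HH5 embryo. Here 1 embryo was cut, so the p-values compare its sections and have no replicate embryo behind them. In the 12 middle sections 1158 genes were higher than in the outer sections and 1415 were lower, among 8345 tested. ENSGALG00000026983 averaged 98.2 ± 192 CPM over the 12 middle sections (SD over sections) against 2.17 ± 2.22 and 1.97 ± 2.06 on the low-numbered and high-numbered sides, because its signal was confined to a few sections around section 20, where it reached 644 CPM. ENSGALG00000028376 was broader, at 46.6 ± 49.4 CPM in the middle and 0.560 ± 0.847 and 1.93 ± 2.74 on the sides (log2 difference 5.51, SE 0.560). Among genes of the flanks, ENSGALG00000038919 had 14.9 ± 7.45 and 14 ± 7.86 CPM on the sides and 0.882 ± 0.874 in the middle (log2 difference -4.04, SE 0.456). ENSGALG00000019290 had 11.2 ± 4.61 and 18.2 ± 17.5 CPM on the sides and 1.16 ± 1.28 in the middle (log2 difference -3.58, SE 0.559). A smooth curve across the axis was called for 3557 of 10021 genes, and 62.2% of these curves correlated at 0.5 or more with their own mirror image. The share that smooth curves of this form give without symmetry was not computed.

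**Figure D3:**
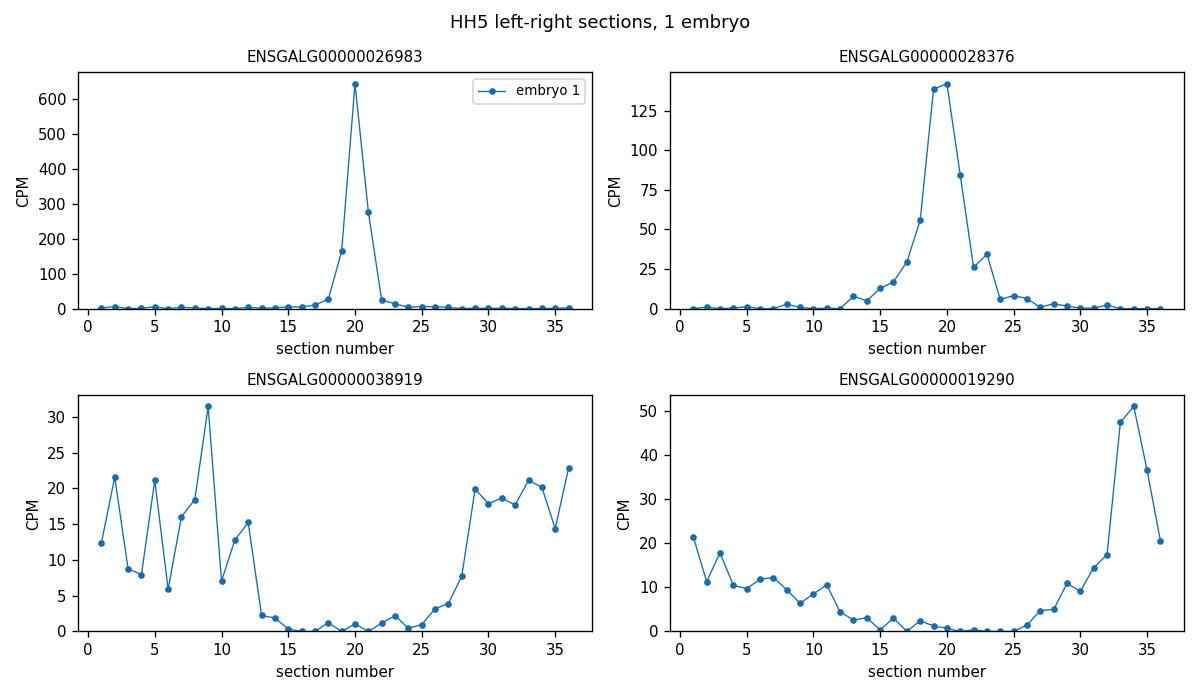
CPM (vertical axes, from 0) by section number (horizontal axes) in the left-right embryo for the 4 genes named in the comparison of middle and outer sections; each point is 1 section. The upper 2 genes peak at section 20 and the lower 2 are near 0 there.

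Asymmetry between the sides was tested at matched distance from the centre of the section numbers. By edgeR's quasi-likelihood test 439 genes were higher on the high-numbered side and 391 on the low-numbered side, with a median absolute log2 difference of 0.50, and 109 of the 830 differed at least 2-fold. Sections 25 to 35, all on the high-numbered side, had a median of 21.4% of reads aligned to several places, against 8.62% in sections 1 to 12, so the side and this property of the libraries cannot be told apart for the outer sections. With that share as a covariate 451 genes were called, 155 higher on the high-numbered side and 296 lower, and 211 of them were among the 830. That covariate was chosen after seeing the data. Moving the assumed centre by 2 sections changed the count to 1366 towards the low-numbered side and to 590, with 252 higher and 338 lower, towards the high-numbered side.

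The amount of added spike-in RNA recovered per gene read also followed position at HH5. ERCC and SIRV molecules are synthetic RNAs added to a sample as a control, and the amount added per section is not given in the sources used here. In embryo 1 the low-numbered segment had 61.8 ± 21.5 spike-in reads per 10000 gene reads (SD over 15 sections), the middle 31.2 ± 10.5 and the high-numbered segment 40.7 ± 12.2. In embryo 2 the values were 72.9 ± 44.1, 43.2 ± 9.97 and 43.3 ± 8.31 over 18 sections each. The lowest value of the left-right series, 12.2, was at section 20. The share of multiply aligned reads followed position as well in embryo 2, with segment medians of 21.2%, 21.2% and 14.8% from low to high numbers, against 10.7%, 8.63% and 8.80% in embryo 1. With that share as a covariate, chosen after seeing the data, 2127 genes had a shared curve, and the comparison of ends was not run with it. Scaling libraries to the spike-ins in place of gene counts moved the median of all genes by 0.59 on the log2 scale in each antero-posterior comparison and by 1.05 in the left-right one. With that scaling, chosen after seeing the data, 3534 genes were higher and 259 lower in the high-numbered segment, 4233 higher and 28 lower in the middle segment, and 6747 higher and 181 lower in the middle of the left-right axis. With library totals alone, also chosen after seeing the data, the ends split into 420 higher and 829 lower. All differences in the preceding comparisons are therefore relative to the typical gene of a section, and not amounts per section.

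**Figure D4:**
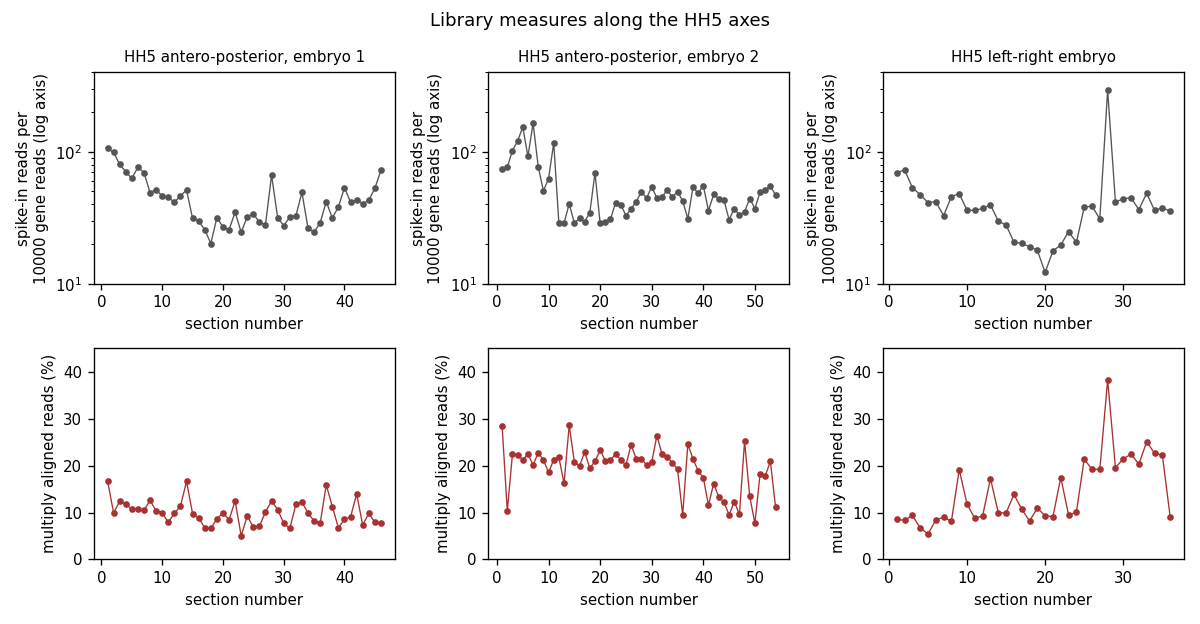
Spike-in reads per 10000 gene reads (upper row, log axis) and percent of multiply aligned reads (lower row) by section number in the 3 HH5 embryos; each point is 1 library. The spike-in share is highest among the low-numbered sections of both antero-posterior embryos, and the multiply aligned share is raised in sections 25 to 35 of the left-right embryo and in the first 2 segments of antero-posterior embryo 2.

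At the earlier stages each gene was given a slope along the antero-posterior sections, as the log2 change from the first to the last section. Section 1 was taken as the same end in both embryos of a stage, which the labels do not state. At HH1 edgeR called 0 of 10020 genes, with 405 at an unadjusted p under 0.05, and DESeq2 called 2. Those 405 are no more than the share of 0.05 that chance alone gives. At HH2, 51 genes rose towards the high-numbered end and 15 fell, and at HH3, 98 rose and 46 fell. Comparing only the last with the first section gave a more even split, with 68 higher and 51 lower at HH2 and 125 higher and 101 lower at HH3. Every gene called by its slope had the same sign in both embryos of its stage, which the joint fit of these embryos favours. ENSGALG00000033786 gave the steepest named HH2 profile, from 7.99 ± 4.28 CPM in section 1 to 21.8 ± 7.75 in section 3 and 1053 ± 171 in section 5 (SD, n = 2 embryos). ENSGALG00000030902 also rose, from 0.636 ± 0.899 to 15.1 ± 10.6 CPM, with 1 of the embryos at 0 in section 1 and slopes of 5.64 in embryo 1 and 2.25 in embryo 2. ENSGALG00000005802 fell from 43.3 ± 25.3 to 4.07 ± 1.93 CPM (slope -3.31, SE 0.550) and ENSGALG00000006728 from 42.5 ± 24.7 to 6.43 ± 5.55 CPM (slope -2.78, SE 0.662), although the slope of the latter was -4.35 in embryo 1 and -0.64 in embryo 2. Its call was lost without the HH2 library of 4327 gene counts (slope -2.76), which was tried after seeing the data, and also without the count filter, with HH2 fitted alone, for last against first section and without embryo 1 (slope -0.92). The call of ENSGALG00000030902 was lost without the count filter, without the block, for last against first section and without either embryo (slopes 3.90 and 8.62), and that of ENSGALG00000033786 without either embryo (7.50 and 9.27). Without HH2 embryo 1 the count was 0 in edgeR, with 454 at an unadjusted p under 0.05, and without embryo 2 it was 37.

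At HH3 the rising genes included ENSGALG00000026467, which also had the high-numbered profile at HH5. Its level was 0.187 ± 0.264 CPM in section 1, 0.963 ± 0.857 in section 4 and 66.4 ± 25.2 in section 6. ENSGALG00000011489 climbed from 7.90 ± 2.55 CPM in section 1 to 205 ± 51.5 in section 4 and 989.6 ± 149 in section 6 (slope 7.61, SE 0.821, adjusted p = 7.08e-06 in edgeR's quasi-likelihood test). ENSGALG00000015895 fell from 62.7 ± 15.8 to 8.15 ± 4.09 CPM (slope -3.01, SE 0.601), and ENSGALG00000015079 from 83.4 ± 33.5 to 10.1 ± 3.44 CPM (slope -2.78, SE 0.387). Without HH3 embryo 1 the calls of these falling genes were lost (slopes -2.18 and -1.84) and the count was 9, and without embryo 2 it was 48. Differences between slopes of these stages were tested directly. No gene passed for HH3 against HH1 or HH3 against HH2 in edgeR, with 510 and 305 genes at an unadjusted p under 0.05, and DESeq2 called 4 and 0. In simulations the test of HH3 against HH1 recovered 9% of differences of 1 and 46% of differences of 2 on the log2 scale. The lack of calls therefore does not show that slopes were equal.

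**Figure D5:**
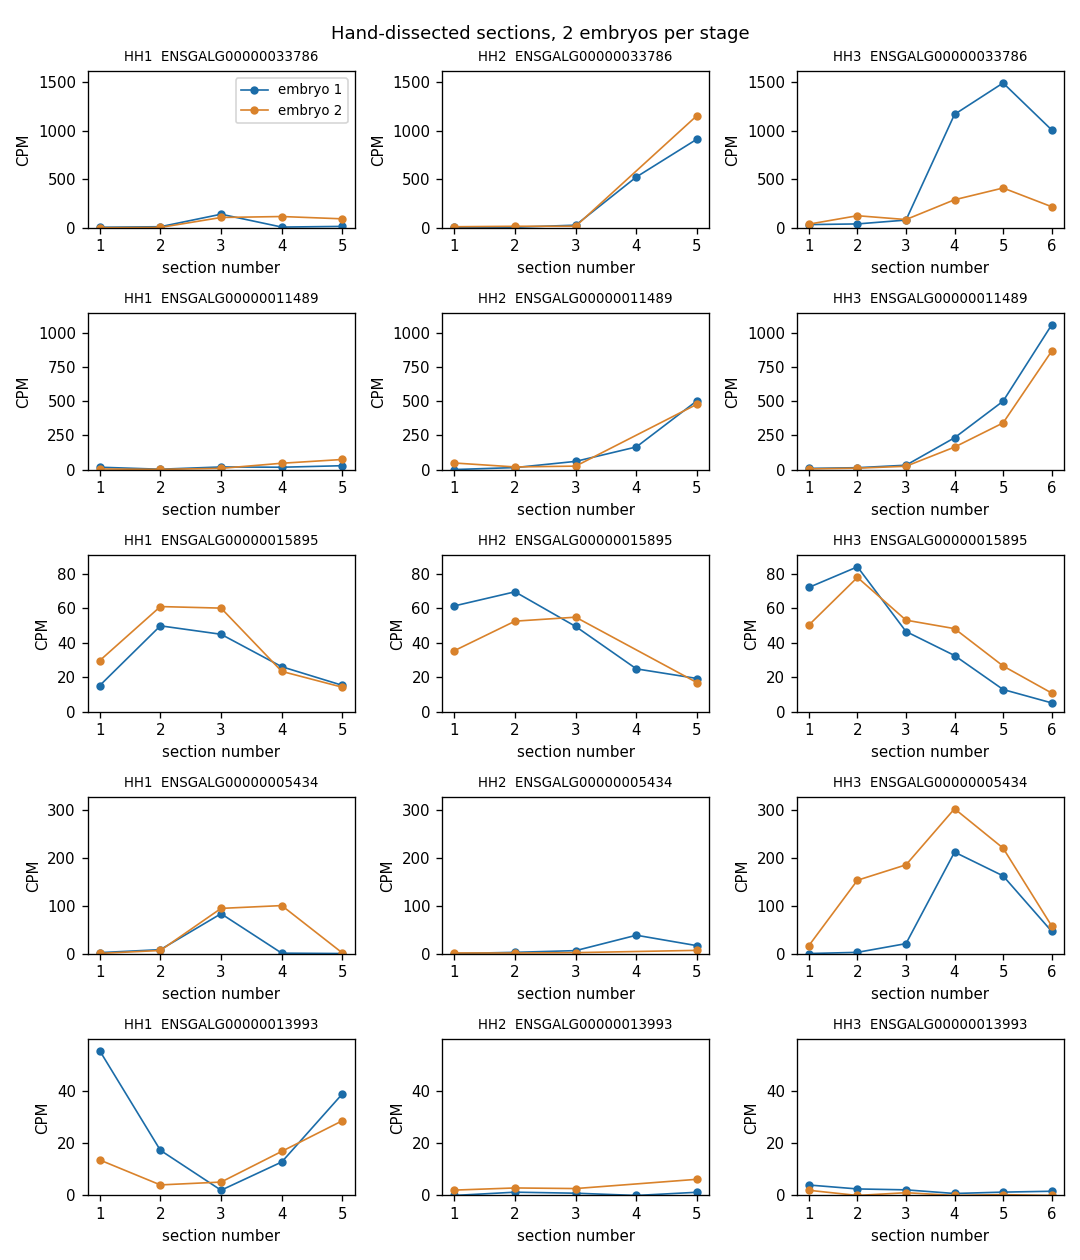
CPM (vertical axes, from 0, on the same scale across each row) by section number (horizontal axes) at HH1, HH2 and HH3; each point is 1 library and each colour 1 embryo, and the HH2 library with 4327 gene counts is left out. ENSGALG00000033786, ENSGALG00000011489 and ENSGALG00000015895 are named in the slope comparisons, and the lower 2 genes come from the comparison of middle and end sections at HH1.

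Gradients of HH3 and HH5 were compared across genes, which are not independent replicates. Over 9984 genes the HH3 slope and the HH5 difference between ends had a Pearson r of 0.335 and a Spearman rho of 0.267. Genes rising towards the high-numbered end at both stages numbered 46 against 4.89 for independent lists, and those falling at both numbered 13 against 2.34. No gene called at both stages went in opposite directions, and 121 of the 143 HH3 genes tested at HH5 (84.6%) had the same sign there, against 58.6% of all genes. For HH2 and HH5 the r was 0.199, and 1 gene called at both went in opposite directions. Of the 66 HH2 genes, 52 (78.8%) had the same sign at HH5, against 57.4% of all genes. Between HH2 and HH3, 34 genes rose in both against 0.499 for independent lists and 6 fell in both against 0.0689, with r = 0.458 across 10020 genes. Both stages come from the same fit and share its estimate of spread for each gene. Across genes, HH1 slopes had an r of 0.244 with HH2 slopes, 0.222 with HH3 slopes and 0.0467 with the HH5 differences, with a rho of 0.187, 0.137 and 0.0205. The slopes of the paired embryos of a stage, and at HH5 their differences between ends, correlated across all genes tested at 0.0655 for HH1, 0.259 for HH2, 0.370 for HH3 and 0.357 for HH5. Across genes of at least 5 log2 CPM the values were 0.0789, 0.484, 0.584 and 0.658. If section 1 were not the same end in both HH1 embryos, their joint slopes and the HH1 comparisons with later stages could be weakened.

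Stages were compared by whole-embryo sums, 2 embryos each. From HH1 to HH2, 3 genes rose and 19 fell among 12538 in edgeR, while DESeq2 called 109 higher and 242 lower. ENSGALG00000011489, one of the graded HH3 genes, rose from 20.3 ± 4.88 to 169.7 ± 29.8 CPM (log2 difference 3.06, SE 0.390), and ENSGALG00000005448 from 3.47 ± 0.0633 to 21.4 ± 1.81 CPM (log2 difference 2.63, SE 0.384). Section 4 holds 4327 of the 12164622 gene counts of HH2 embryo 2, so that its sum practically lacks that section, and with all sections scaled to equal totals the log2 difference of ENSGALG00000005448 was 3.73 and did not pass. In edgeR that scaling called 0 genes, with 1678 at an unadjusted p under 0.05. It gives those 4327 counts the weight of a whole section, so the noise of a failed library enters both values and the scaling does not make up for the missing section. ENSGALG00000011668 had 1000 counts over the HH1 libraries and 2 over the HH2 libraries, a ratio per gene count of 447 with a 95% exact binomial interval of 123 to 3697 for counting error only. ENSGALG00000000379 fell from 46.2 ± 0.601 to 4.38 ± 0.138 CPM (log2 difference -3.40, SE 0.551), and its call was lost with RLE size factors (log2 difference -3.37), which called 18 genes. These 22 calls lay close to the threshold, with a smallest adjusted p of 0.0402 in edgeR, and the count was 0 in edgeR when any 1 of the 4 embryos was left out, with 804 to 1470 at an unadjusted p under 0.05, and 351 in DESeq2 with every embryo. Between HH2 and HH3 edgeR called 0 genes, with 456 at an unadjusted p under 0.05, and DESeq2 called 36.

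From HH3 to HH5, 250 genes rose and 107 fell. ENSGALG00000015143 went from 6.85 ± 0.212 to 1038 ± 179 CPM (log2 difference 7.24, SE 0.380, adjusted p = 2.17e-05 in edgeR's quasi-likelihood test), and ENSGALG00000016491 from 0.303 ± 0.13 to 44.6 ± 38.9 CPM (log2 difference 7.19, SE 0.940). ENSGALG00000005434 fell from 110.5 ± 57.7 to 1.42 ± 0.979 CPM (log2 difference -6.28, SE 0.859) and ENSGALG00000037408 from 158 ± 37.2 to 2.66 ± 0.908 CPM (log2 difference -5.89, SE 0.785). The HH5 embryos were cryosectioned and the HH3 embryos dissected by hand, so stage and collection cannot be told apart here. The count was 63 without HH3 embryo 2, 105 without HH3 embryo 1 and 1046 without HH5 embryo 2, and 989 in DESeq2; the call of ENSGALG00000037408 was lost without either HH5 embryo (log2 differences -6.29 and -5.57).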

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

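The patterns weighed here were picked after the comparisons had been computed. The test bounds were set before the test values were known, although the counts with a covariate and with moved centres had been seen, and the tests of particular libraries, of sections 1 and 36 and of 1 library per bin were chosen after the results were seen.

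Between the sides of the left-right embryo 830 genes differed. Swapping sections of equal distance from the centre at random gave at most 460, so that 1 of 100 splits, the real one, was as large. Random swaps within this embryo are thus an unlikely source of the count, but variation between embryos cannot be tested with 1 embryo. A library batch in sections 25 to 35, which have more multiply aligned reads, could give such differences: of 942 genes called from sections 1 to 12 against 25 to 36, 65.4% kept their direction between sections 13 to 18 and 19 to 24, between the bounds of 60% for and 70% against a batch, and 8 of the 64 swaps of these inner sections, the real one included, reached that share. Of 1080 genes called without sections 1 and 36, 51.8% kept their direction between those sections. A midline away from the centre could contribute as well, since the spike-in share was lowest at section 20, but side and middle differences, computed from the same libraries, correlated across 8345 genes at 0.172, between the bounds set for and against it. Library batch, an off-centre midline and asymmetry of the embryo, which was not tested in a replicate, cannot be told apart for these genes.

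More genes were graded at HH5 than at HH3, and finer sampling is a candidate explanation. When each HH5 embryo was summed into 6 bins and thinned to the HH3 median of 2782385 gene counts, 524 genes were called against 179 for HH3 fitted alone, a ratio of 2.93 above the bound of 1.5 set beforehand, and without thinning the bins gave 794. Each bin averages several libraries, however, and with 1 library drawn at random per bin, at no more than the HH3 depth, the median over 20 draws was 73 genes (11 to 209), which a single cryosection holding less RNA could also bring about. Sampling is therefore not excluded as the source of the whole difference. Stage and the change from hand dissection to cryosections remain open too, as both differ between these embryos, and neither was tested.

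In segment means, low-numbered sections at HH5 gave fewer gene reads per spike-in, so the amount of RNA could have shaped the differences between ends. In embryo 2 this did not hold for the whole low-numbered segment. There section 11 had 117 spike-in reads per 10000 gene reads, but section 12 had 28.7 and section 17 had 29.5. The means of its middle and high-numbered segments were 43.2 and 43.3. As the amount of spike-in added per section is not given, this share does not establish RNA content. If RNA amount acted, genes called between the ends should have moved the same way between the middle of the left-right embryo, which had fewer spike-in reads per gene read, and its flanks. Of 978 such genes, 55.9% moved that way, against 52.1% of all genes tested in both, under the bound of 60% set beforehand. The left-right middle and flanks also differ in position, however, so this share cannot isolate an effect of RNA amount. Of 1068 genes with a shared curve peaking in the low-numbered segment, 513 were lower in the left-right middle, against 181 for independent lists, and 201 were higher against 149. RNA amount therefore stays open. No order of sections drawn at random gave any gene with a shared curve, so that 1 of 40 orders, the real one, reached 2030. A chance order of the sections in these embryos is thus an unlikely source of the curves, while variation between further embryos was not tested. Position along the embryo stays open as the biological explanation, as does the embryo edge that the outermost sections hold.

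Single libraries also stood apart. HH2 embryo 2 section 4 had 4327 gene counts against 2387750 in the next lowest of 10 HH2 libraries, 1858 detected genes against 11484, and 41.6 spike-in reads per 10000 gene reads. At HH1, embryo 2 section 3 had the most gene counts, 4186834, and embryo 1 section 4 had 25.2 spike-in reads per 10000 gene reads against at most 12.2 in the other HH1 libraries. Of 10 group and measure combinations examined for a lone extreme value, chance alone marks about 1 in 20. Left-right section 28 had 293 spike-in reads per 10000 gene reads, against at most 73.0 in the other sections of that embryo. In HH5 antero-posterior embryo 2, section 36 had 63.1% of its reads outside annotated features, against at most 29% elsewhere in that embryo, and 17551 detected genes.

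One gene, ENSGALG00000013929, differed in slope between HH2 and HH1 by 9.44 on the log2 scale (adjusted p = 0.0192 in edgeR, and 1 gene in DESeq2 as well), and it was the 1 call among 10020 genes; it is named here because of that call. It was found in all 10 HH1 libraries, with 4 to 32 counts, while at HH2 it had 0 counts in sections 1 to 3 of both embryos and 14 and 16 in section 5. The fitted size depends on the prior count because of those zeros. Without the failed library of HH2 embryo 2 the adjusted p was 0.0302.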

How the results depend on the processing

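The spike-in, covariate and single-library settings below were chosen after seeing the data. Genes named in the comparisons of the report kept their sign in the settings run on them, and the 4 genes of the HH1 middle were not followed. Among genes called both ways, 466 of 1805 had the opposite sign in the left-right middle with spike-in scaling, and 1 of 572 and 9 of 323 between the sides with the centre moved 2 sections down and up. Where no cause is named the cause was not tested.

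Leaving out the block of embryo ended the HH5 calls, with 0 genes in edgeR for the ends and 0 for the middle (767 and 344 at an unadjusted p under 0.05; DESeq2 with the block 1451 and 600), and gave 43 at HH2 and 84 at HH3 for the slopes, while the paired fit is the one reported. Blocking stage sums by embryo number gave 0 genes for HH2 against HH1 (1243 unadjusted) and moved no other stage count by over 1.5 times. Treating sections as samples raised the ends to 3029 and the middle to 1775, with 9142 genes tested in place of 14192. Single embryos fitted by sections gave 2072 to 2321 genes for the ends, 792 to 968 for the middle and 3554 to 4938 for curves. Spike-in scaling gave 3793, 4261 and 6928 genes for the HH5 ends, middle and left-right middle. Requiring a curve correlation of 0.8 left 1189 shared curves. Without the count filter there were 761 genes for the middle, 6885 left-right curves, and 415, 75 and 1148 genes for the successive stage steps. The sides gave 1366 genes with the centre 2 sections lower and 451 with the multiply aligned share as covariate.

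The HH1 slope, 0 genes, became 2 in DESeq2, 1 with HH1 alone, 3 for last against first section and 1 to 4 without an embryo. Last against first section gave 119 genes at HH2 and 226 at HH3, and leaving out an embryo 0 to 37 and 9 to 48. DESeq2 called 4 genes for HH3 against HH1 slopes and 351, 36 and 989 for the stage steps. Stages fitted in pairs gave 96 for HH2 against HH1 and 216 for HH5 against HH3. Sections scaled to equal totals gave 0 for HH2 against HH1 (1678 unadjusted), with the noise of the failed HH2 library scaled up, as did leaving out any embryo (0 to 0); the ranges were 0 to 1 for HH3 against HH2 and 63 to 1046 for HH5 against HH3, and adding the left-right embryo gave 987. The gradient correlation of 0.335 was 0.250 to 0.302 without an embryo and 0.534 among genes called in either stage.

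All other settings kept their counts within 1.5 times. The planned gene list tests were not run, as no identifier had a symbol. No left-right library was below 10% of the median depth, so leaving such libraries out changed nothing there. At these depths and numbers of libraries small changes were often missed: in simulations 24% of HH1 slopes of 1 on the log2 scale were recovered.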

Other observations

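The HH1 sections were also compared from centre to edge, which was chosen after a principal component of the same libraries had shown such a pattern. The p-values measure how far the paired embryos of a stage disagreed at the same section, pooled over HH1, HH2 and HH3. Comparing section 3 with the mean of sections 1 and 5 in edgeR, 704 genes were higher in the middle and 346 were lower, among 10384 tested. The median absolute log2 difference of these 1050 genes was 1.17. Of them, 1044 had the same sign in both embryos, which the joint call favours. Across genes of at least 5 log2 CPM, the differences of the paired embryos had a Pearson r of 0.378. The section 3 library of embryo 2 had the most gene counts, 4186834, and the most detected genes, 13417, of the HH1 libraries. It also had the lowest share of multiply aligned reads and the highest share outside annotated features at HH1. As each embryo gives 1 library of section 3, the part of this library in the count cannot be told apart. ENSGALG00000001900 had 35.6 ± 23.8 CPM in section 3 (SD, n = 2 embryos) against 0 in section 1 and 0.217 ± 0.306 in section 5. ENSGALG00000005434, which later fell from HH3 to HH5, had 91.4 ± 8.34 CPM in section 3 against 1.12 ± 1.15 and 0.543 ± 0.768 at the ends. In section 4 it had 52.1 ± 72.6 CPM, so the embryos differed widely there. In the opposite direction, ENSGALG00000013993 went from 35.4 ± 30.3 and 34.6 ± 7.43 CPM at the ends to 3.68 ± 2.29 in section 3, and ENSGALG00000037494 from 32 ± 20.4 and 38.2 ± 22.2 to 6.46 ± 2.12. Since the pattern had been seen in these libraries, the count of 1050 genes describes it and cannot test whether HH1 embryos are organised from centre to edge, and end-to-end gradients are not excluded. Of 99 random orders of the sections 18 gave HH1 slopes, up to 367 genes. The count was 1118 in DESeq2. With either HH1 embryo left out, each HH1 section holds 1 library and the spread comes from HH2 and HH3 alone, so those counts are not given. The same comparison gave 293 genes at HH2, and with the mean of sections 3 and 4 against the mean of sections 1 and 6 it gave 454 at HH3.

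The remaining comparisons of this part, except the random orders, were also chosen after seeing the data. Genes of the HH1 centre overlapped with those of later middles. The HH2 and HH3 middles come from the same fit as HH1 and share its estimate of spread for each gene. With HH2 the overlap was 96 higher in both against 9.29 for independent lists and 77 lower in both against 5.2, with 1 in the opposite direction. Of the genes higher in the middle at HH1, 176 were also higher in the middle at HH3, against 18.6, and 87 were lower in both against 5.96, with 0 in opposite directions. With the left-right middle of HH5 the overlap was 209 higher in both against 87.3 and 121 lower in both against 52.5, but 129 genes went in opposite directions. With the antero-posterior middle of HH5 it was 60 against 11.3 and 57 against 8.58, and 27 genes went in opposite directions. How many opposite directions independent lists would give was not computed for these overlaps, so the opposite counts cannot be read as conflicts.

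The middle of the antero-posterior axis and the middle of the left-right axis at HH5 shared their genes, although they come from different embryos. Of 162 genes higher in the antero-posterior middle and tested on both axes, 120 were also higher in the left-right middle, against 22.5 for independent lists, and 4 were lower. Of 261 genes lower in the antero-posterior middle, 226 were lower in the left-right middle, against 44.3, and 1 was higher. The log2 differences correlated across 8345 genes at r = 0.593. Before this was computed, the hypothesis that genes of the antero-posterior middle are medial was given a bound. It asked for 70% of them with a positive left-right difference, and 91.4% had one, against 48% of all genes. Both comparisons set inner sections against outer ones, which include the embryo edge. The share therefore cannot tell medial genes from genes that are low at the edge. The left-right middle and the middle of antero-posterior embryo 1 had fewer spike-in reads per gene read than their ends, so RNA amount may enter this overlap; in embryo 2 the middle and the high-numbered segment had nearly equal shares. Genes with shared curves that peak in the middle segment were called higher in the left-right middle in 239 of 393 cases, against 54.9 for independent lists, and lower in 11 against 66.8. Of 1068 that peak in the low-numbered segment 513 were lower there against 181 and 201 higher against 149, and of 441 that peak in the high-numbered segment 113 were lower against 74.9 and 87 higher against 61.6. For the low-numbered and high-numbered peaks, both directions thus exceeded independent lists.

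Sections of the HH5 antero-posterior embryos were matched by their expression, although section numbers entered through the choice of genes. Over 3416 genes with a curve in embryo 1, the section of embryo 2 that each section of embryo 1 resembled most had a relative position that followed its own with a Spearman rho of 0.980, and the median distance was 0.0480 of the axis. The correlations with the best match ran from 0.146 for section 46 to 0.666 for section 2, and several high-numbered sections shared section 45 of embryo 2 as their match. Section 1 of both HH3 embryos and of both HH2 embryos resembled the first of 6 HH5 bins most, although HH2 embryo 2 came close to a tie, with an r of 0.357 for the first bin and 0.347 for the last, whereas section 1 of both HH1 embryos, like section 5, resembled the last bin.

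Random orders of the sections gave at most 3 genes for the HH2 slope and 3 for the HH3 slope, against 66 and 144. In each case 1 of 100 orders, the real one, was as large, so a chance order of sections is an unlikely source of these counts. For the left-right curve the highest other count was 47 against 3557 (1 of 40 orders). For the left-right middle, with sections assigned at random to 3 sets, it was 22 against 2573 (1 of 100 splits), so a chance order or assignment of sections is unlikely there as well. Such shuffles concern the order of sections within these embryos. They exclude neither variation between embryos nor a technical drift from one end of a series to the other.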
